A study of Mus musculus with 27 samples.

How the data were processed

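The series measured messenger RNA by sequencing in mouse T cell models of TAL1, a transcription factor switched on in many cases of T cell acute lymphoblastic leukaemia, and of AKT(E17K), an activated form of the kinase AKT1. Thymus was collected from C57BL/6 mice after bone marrow transplantation, with 3 mice in each of 4 groups, which the labels name as empty vector, TAL1, AKT(E17K), and AKT(E17K) with TAL1. A second system was the ProT cell line, in which the labels describe TAL1 as induced with 4-hydroxytamoxifen, with 3 libraries at each of 0, 6, 12, 18 and 24 h. This gave 9 groups and 27 libraries, and each library had 1 column in 1 of 3 tables (AKT(E17K) mice with and without TAL1, empty-vector and TAL1 mice, and ProT cells). Per the labels' protocols, RNA was extracted with the Promega Maxwell simplyRNA chemistry and sequenced as Illumina libraries. The labels did not say whether the 3 ProT libraries of a time came from separate cultures, so p-values for ProT cells measure only the spread between these samples, which may be technical.

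The deposited values were whole-number counts per gene, not normalized. Per the submitters' processing notes, the tools used were FastQC, HISAT2, SAMtools and HTSeq, and the builds named were mm10 and GRCm38. Their versions, the annotation release and the strand setting were not given in the sources used here. Reads from genes that overlap on either strand, and from near-identical copies such as histone, haemoglobin and Gimap genes, may therefore be split or lost, and such genes are reported as uncertain. The tables with empty-vector mice and with ProT cells each held 46078 gene identifiers with symbols, of which 45143 were found in the GENCODE M21 annotation of GRCm38, the source of every position given here. They also held 5 HTSeq summary lines, which were left out of library sizes and tests. As a share of counts in genes and in these lines together, reads in no annotated feature came to 33.0% in each empty-vector mouse. They came to 29.8% to 30.3% in the mice labelled TAL1 and 17.3% to 22.6% in ProT cells. Ambiguous reads came to 4.67% to 5.13% in empty-vector mice, 5.42% to 6.09% in mice labelled TAL1 and 3.33% to 4.63% in ProT cells. Both shares thus separated the mice labelled TAL1 from the empty-vector mice. Reads not aligned came to 13.5% to 18.8% in these mice and 8.12% to 11.6% in ProT cells. Reads aligned more than once came to 10.3% to 11.6% and 12.7% to 15.4%. The table of AKT(E17K) mice held 22906 symbols with no identifiers, no summary lines and no mitochondrial genes, and 22729 of these symbols occurred as unique symbols in the table of empty-vector mice. In each of the other tables, 27 symbols that a spreadsheet had turned into dates were restored from their identifiers.

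Genes were tested from the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the filterByExpr filter and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The mice labelled TAL1 were compared with those labelled empty vector, and the mice labelled AKT(E17K) with TAL1 with those labelled AKT(E17K), each within its own table. ProT libraries were fitted together, so that all 15 shared 1 estimate of the spread, and each time was compared with 0 h, along with a test over all times. A contrast between the effect of the TAL1 label with and without AKT(E17K) was fitted over the 12 mice on genes present in both tables. The filter left 9782 genes for the AKT(E17K) mice, 12357 for the empty-vector and TAL1 mice, 13610 for ProT cells and 10947 for the contrast. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of F. Levels are CPM, counts scaled by the total over genes that passed the filter times the TMM factor of the library, given as mean ± SD over 3 libraries. Where a gene had a count of 0, the floor was set at 3 counts over the total of all counts in genes, without that factor. Floors and intervals cover counting error only.

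Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, for lists with at least 3 tested members, two-sided, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. There were 32 lists with 508 genes, 44 of them in more than 1 list. They covered TAL1 complex partners with the core leukaemia circuit, TAL1 target genes, early thymic progenitors, T lineage commitment, double-positive thymocytes, mature T cells, T cell receptor signalling, E protein targets, NOTCH1 targets, MYC and ribosome biogenesis, DNA replication, mitosis, FOXO targets, PI3K/AKT components, glycolysis, cholesterol synthesis, ATF4 and amino acid genes, p53 targets, type I interferon response, immediate early genes, the BCL2 family and mitochondrially encoded mRNAs. The other lists held markers of B cells, myeloid cells, dendritic cells, erythroid cells, megakaryocytes with mast cells, NK and innate cells, thymic epithelium, stroma, endothelium and adipocytes. Pairs of lists with the most genes in common were T lineage commitment and NOTCH1 targets (6), mature T cells and FOXO targets (5), and double-positive thymocytes and E protein targets (5).

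The groups, the tests, the lists and the rule for naming genes were set before the data were examined. The rule takes Tal1 and Akt1, with a further gene that is not reported here, then the 8 higher and 8 lower called genes of largest absolute log2 fold change with a mean of at least 5 CPM and no overlap between groups, and then up to 4 members per list with the smallest p, called members first. Unnamed gene models, clones, pseudogenes, receptor gene segments, Xist and Y-linked genes were left out of the ranking. For ProT cells the ranking applied at 24 h, and at 6 h for the 4 higher and 4 lower. The totals over named genes under alternative settings also took in genes ranked in the same way at 12 and 18 h. Genes named outside the rule are marked as chosen after their values were seen. Overlaps of calls between comparisons were tested with two-sided Fisher exact tests over 12 pairs of directions.

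Counts of called genes were recomputed with DESeq2 1.42.0, with RLE size factors, with library size only, with no filter on low counts, with a filter at a mean of 5 CPM, with a required absolute log2 fold change of 1, and without each library in turn. Named genes were recomputed in the same ways except for the fold change limit, lists in the same ways except for that limit and DESeq2, and overlaps only with DESeq2 and with the limit. For ProT cells a fit with the replicate number as a block and a fit on only the groups compared were added. Alternatives chosen after seeing the data thinned every library to the shallowest of its table, left out the abundant genes Rn18s-rs5 and Yam1, left out 0 h library 1 and 6 h library 1 of ProT cells together, which lay apart from their replicates on a principal component, and compared consecutive times. Replicates were checked for duplicate libraries by a chi-square test of their counts, which gave 2.39 to 37.7 per degree of freedom, so none were treated as 1 sample.

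The steps were tested on simulated data with 200 changed genes drawn from the real means and depths, in 1 draw per comparison. For the AKT(E17K) mice, 60.9% of genes changed by a log2 fold of 2 and 5.97% of those changed by 1 were recovered over 9622 simulated genes. For the empty-vector and TAL1 mice these shares were 82.3% and 56.9% over 12050 genes, for ProT cells at 24 h they were 92.4% and 71.6% over 13432 genes, and for the contrast they were 48.4% and 5.97% over 10731 genes. False calls made up 4.35%, 11.9%, 6.35% and 2.78% of the calls. With DESeq2 they made up 18.3% of the calls for the AKT(E17K) mice, 15.6% for the empty-vector and TAL1 mice and 8.59% for ProT cells at 24 h.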

Results

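RNA sequencing counts were analysed for 27 mouse libraries in 9 groups of 3. The title given by the submitters asks whether TAL1 acts together with the PI3K/AKT pathway in T cell acute lymphoblastic leukaemia, a cancer of developing T cells. Thymus from 12 transplanted mice made up 4 groups, labelled empty vector, TAL1, AKT(E17K), and AKT(E17K) with TAL1. ProT cells, a mouse T cell precursor line, made up 5 groups, taken 0, 6, 12, 18 and 24 h after 4-hydroxytamoxifen, which the labels describe as inducing TAL1 by way of CreER and LoxP. Depth was lowest in the AKT(E17K) experiment, with 2073752 to 3661056 counts in genes per mouse without TAL1 and 2230143 to 2792084 with it. The empty-vector mice had 3893990 to 5915285 counts and the mice labelled TAL1 had 7155918 to 11302098. ProT libraries had 2660641 to 5367020 counts at 0 h, 4820586 to 5961536 at 6 h, 4649416 to 6599146 at 12 h, 4037467 to 5779420 at 18 h and 4614643 to 6258268 at 24 h. The biological coefficient of variation between replicates was 35.0% in the AKT(E17K) experiment, 22.0% in the empty-vector experiment and 11.6% in ProT cells. The ProT libraries could resolve smaller changes. Levels are in CPM, counts scaled by library totals with TMM factors, as mean ± SD with n = 3.

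Tal1 itself (chromosome 4, 115056426 to 115071755, GRCm38) did not follow the labels. No count fell on Tal1 in any of the 3 mice labelled TAL1, the 3 labelled AKT(E17K) with TAL1 or the 3 labelled empty vector. The only thymus with Tal1 counts was AKT(E17K) mouse m121, with 7 counts (2.24 CPM). On totals without TMM factors, a count of 0 allowed at most 0.116 CPM over the pooled mice labelled TAL1, 0.390 CPM over those labelled AKT(E17K) with TAL1, and 0.207 CPM over the empty-vector mice. It allowed 1.45 and 0.819 CPM in AKT(E17K) mice m122 and m124. A TAL1 sequence outside the counted Tal1 gene would not be seen in these values. The groups are therefore named by their labels. In ProT cells Tal1 was among the abundant genes at 0 h, with 2895, 3028 and 3098 CPM in the 3 libraries. It was 3033, 3608 and 3045 CPM at 6 h, 2259, 2227 and 1779 at 12 h, 2149, 2233 and 2358 at 18 h, and 2068, 2026 and 1963 at 24 h.

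Tal1 counts thus did not rise after tamoxifen. The log2 fold change against 0 h was 0.10 at 6 h (adjusted p = 0.941), -0.53 ± 0.12 at 12 h (adjusted p = 0.00509), -0.42 at 18 h (adjusted p = 0.0299) and -0.57 ± 0.12 at 24 h (adjusted p = 0.00172, edgeR, ± SE). With scaling by library size only, Tal1 fell by 0.38 on the log2 scale at 24 h (adjusted p = 0.0223). The call was lost at 12 h (-0.34, adjusted p = 0.0541) and at 18 h (-0.27, adjusted p = 0.146). The 18 h call also ended without any of the 6 libraries behind it. The adjusted p values were 0.0633, 0.098 and 0.0815 without 0 h library 1, 2 or 3, and 0.142, 0.094 and 0.0568 without 18 h library 1, 2 or 3. Akt1 (chromosome 12, 112653821 to 112674884), which encodes the kinase mutated in AKT(E17K), was 78.2 ± 30.6 CPM in AKT(E17K) mice and 84.5 ± 2.90 CPM in those labelled AKT(E17K) with TAL1 (log2 fold change 0.12, adjusted p = 0.947). It was 138 ± 17.7 CPM in empty-vector mice and 139 ± 18.1 CPM in mice labelled TAL1 (0.02, adjusted p = 0.973). The tables of these experiments are separate, so these Akt1 levels are not compared across them.

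**Figure D1:**
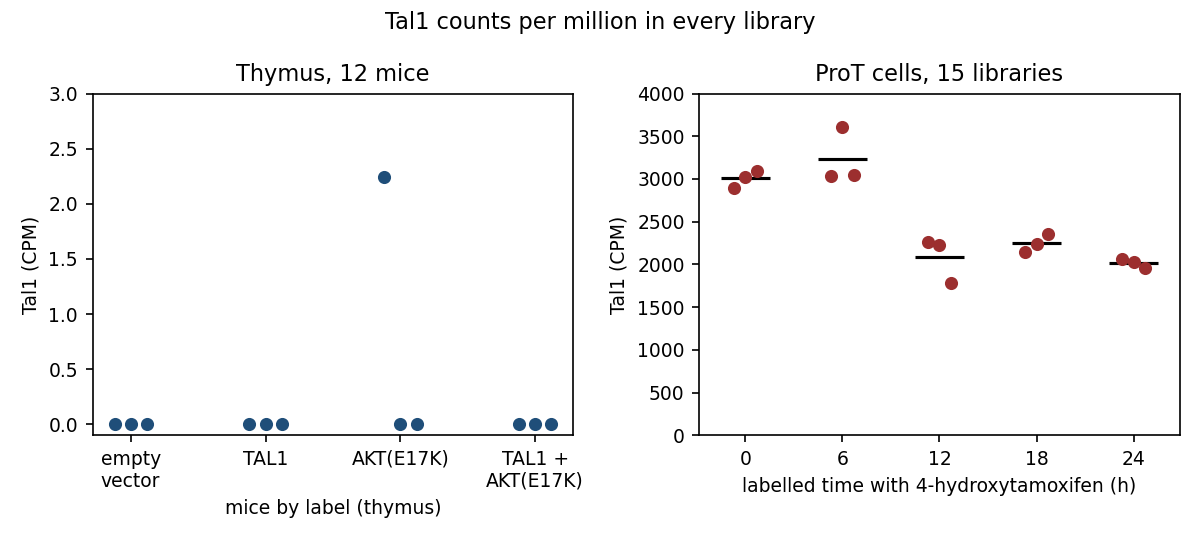
Tal1 level in CPM in each library, with the 12 thymus mice by label on the left and the 15 ProT libraries by hours after tamoxifen on the right, where lines mark group means. The thymus values were 0 except for 2.24 CPM in AKT(E17K) mouse m121, and the ProT means went from 3007 CPM at 0 h to 2019 CPM at 24 h.

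Members of the mature T cell and interferon lists were lower in thymus labelled TAL1 than in empty-vector thymus (12 of 18 and 14 of 20), and members of the DNA replication and mitosis lists were higher (13 of 20 and 13 of 21). Each of these list calls was lost with an estimated correlation (adjusted p = 0.352). Il7r, the interleukin-7 receptor of resting T cells (chromosome 15, 9505788 to 9530176), fell from 131 ± 21.5 to 36.3 ± 5.48 CPM (log2 fold change -1.84 ± 0.16, adjusted p = 0.000219). S1pr1, the receptor with which mature thymocytes leave the thymus (chromosome 3, 115710433 to 115715072), fell from 79.3 ± 2.81 to 8.20 ± 5.13 CPM. Top2a, a topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), rose from 1029 ± 59.8 to 1761 ± 184 CPM. Because Tal1 had no counts in either group, each of these directions rests on the labels alone.

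Of 12357 genes tested with edgeR, 267 were higher and 356 lower in the mice labelled TAL1, 623 in all. Of these, 238 changed by at least 1 on the log2 scale (22 higher, 216 lower). The count fell to 337 without empty-vector mouse M312, 359 without M315, 403 without TAL1 mouse M317 and 356 without M318. Named genes made up 256 of the higher calls and most of the lower calls. The remainder were gene models, clones, pseudogenes and 1 receptor segment. Unless a value is given, the genes named for this comparison kept their call without any 1 mouse.

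Most mature T cell genes were lower: 12 of 18 tested members were lower, none higher and 6 not called. When adjusted over the list alone 16 were lower (mean log2 fold change -1.97, camera adjusted p = 1.27e-12, adjusted p = 0.352 with an estimated correlation). Besides Il7r and S1pr1, Klf2, a transcription factor that keeps T cells quiescent (chromosome 8, 72319033 to 72321656), fell from 144 ± 25.5 to 35.5 ± 10.5 CPM. Gimap4, of a family of lymphocyte GTPases with similar sequences, fell from 168 ± 17.9 to 33.4 ± 22.4 CPM. Among type I interferon genes 14 of 20 were lower, none higher and 6 not called (14 lower adjusted over the list alone, mean -1.82, camera adjusted p = 7.48e-13, adjusted p = 0.352 with an estimated correlation). Ifit1, which binds viral RNA (chromosome 19, 34640871 to 34650009), fell by 2.83 on the log2 scale, and Ifi27l2a was at -2.82, Rtp4 at -2.21 and Xaf1 at -2.12. FOXO targets, which AKT signalling represses, had 5 of 18 lower and none higher (2 higher and 8 lower adjusted over the list alone, mean -0.60, camera adjusted p = 0.0193, adjusted p = 0.424 with an estimated correlation). Of those 5, 4 are also in the mature T cell list. The FOXO target list lost its call without empty-vector mouse M312 (adjusted p = 0.0515) or M315 (adjusted p = 0.0639). T cell receptor signalling had 4 of 23 lower and none higher (1 higher and 8 lower adjusted over the list alone, mean -0.27, camera adjusted p = 0.0164, adjusted p = 0.758 with an estimated correlation). Its call ended without empty-vector mouse M312 (adjusted p = 0.129) or M315 (adjusted p = 0.0547) and without TAL1 mouse M318 (adjusted p = 0.2). Its member Cd2, an adhesion receptor of T cells (chromosome 3, 101275899 to 101287939), fell from 311.6 ± 34.9 to 177 ± 35.3 CPM (adjusted p = 0.00542).

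Members of cell cycle, cholesterol and immature thymocyte lists were called higher. DNA replication genes had 13 of 20 higher and none lower (18 higher adjusted over the list alone, mean 0.65, camera adjusted p = 9.57e-14, adjusted p = 0.352 with an estimated correlation). Rrm2, a subunit of the enzyme that makes deoxynucleotides (chromosome 12, 24708241 to 24714146), rose from 103 ± 8.39 to 199.7 ± 12.7 CPM. Uhrf1 rose from 110.3 ± 5.15 to 199 ± 25.6 CPM and Ccne2, a cyclin of S phase entry, from 53.8 ± 7.52 to 107 ± 9.36 CPM. Mitosis genes had 13 of 21 higher and none lower (18 higher adjusted over the list alone, mean 0.64, camera adjusted p = 3.12e-13, adjusted p = 0.352 with an estimated correlation). Among them were Mki67 (0.76), Plk1 (0.78) and Nusap1 (0.79). Cholesterol synthesis had 4 of 20 higher and none lower (8 higher adjusted over the list alone, mean 0.74, camera adjusted p = 3.73e-10, adjusted p = 0.352 with an estimated correlation). Its member Hmgcs1 rose by a log2 fold change of 1.02 ± 0.15. Genes of double-positive thymocytes, the stage before mature T cells, had 6 of 18 higher and none lower (11 higher and 1 lower adjusted over the list alone, mean 0.28, camera adjusted p = 0.000147, adjusted p = 0.352 with an estimated correlation). Mns1 rose by 0.84 and Dntt, which adds nucleotides to receptor joints, by 0.61. MYC and ribosome biogenesis genes had 1 of 22 higher (4 adjusted over the list alone, mean 0.29, camera adjusted p = 0.000561, adjusted p = 0.472 with an estimated correlation).

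Other lists were not called by camera at the preset correlation, although some members were. Among PI3K/AKT components (24 tested, 2 lower, 3 lower adjusted over the list alone, mean -0.17, camera adjusted p = 0.0846), Pik3cd, a catalytic subunit of PI3K in lymphocytes, fell from 239 ± 12.6 to 106 ± 6.17 CPM. Foxo1 fell from 179 ± 16.1 to 102 ± 7.45 CPM. In the BCL2 family (13 tested, 2 lower, 4 lower adjusted over the list alone, mean -0.39, adjusted p = 0.428), Bcl2, which protects cells from apoptosis, fell by 1.30 on the log2 scale. TAL1 complex partners had 2 of 15 lower (1 higher and 3 lower adjusted over the list alone), Id2 and Runx3, with a mean of -0.20 but a median of 0.13 and an upward test direction (adjusted p = 0.855). TAL1 target genes had 1 of 13 higher and 4 lower (3 higher and 4 lower adjusted over the list alone, mean -0.34, adjusted p = 0.547). Cd53 and Ccr7, counted among genes that TAL1 activates, fell by 1.84 and 2.46. Early progenitor genes had none of 6 called (mean -0.43, adjusted p = 0.349). T lineage commitment genes had none of 18 (3 higher adjusted over the list alone, mean 0.13, adjusted p = 0.506). E protein targets had 2 of 15 higher and 1 lower (4 and 3 adjusted over the list alone, mean 0.06, adjusted p = 0.554). NOTCH1 targets had 2 of 10 lower (3 adjusted over the list alone, mean -0.23, median 0.06, adjusted p = 0.339). Glycolysis had none of 17 called (5 higher adjusted over the list alone, mean 0.15, adjusted p = 0.408). Not called either were p53 targets, none of 16 (mean 0.08, adjusted p = 0.69) and mitochondrially encoded mRNAs none of 13 (mean 0.03, adjusted p = 0.712). ATF4 genes had 1 of 17 higher (1 adjusted over the list alone, mean 0.02, adjusted p = 0.438). Immediate early genes had 2 of 18 lower (4 higher and 5 lower adjusted over the list alone, mean -0.04, adjusted p = 0.438).

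Markers of other cell types did not pass the list test in this comparison. B cell markers had none of 4 called (mean -0.23, adjusted p = 0.622), with Ighm at 367 ± 112 and 397 ± 53.4 CPM. Myeloid markers had none of 5 called (mean 1.79, adjusted p = 0.775). S100a8 reached 160.0 CPM in TAL1 mouse M318 against 2.14 and 1.08 CPM in mice M317 and M319. Dendritic markers (10 tested, mean -0.39, adjusted p = 0.587), erythroid markers (7, mean 0.26, adjusted p = 0.554) and thymic epithelial markers (4, 1 lower adjusted over the list alone, mean -0.36, adjusted p = 0.517) had no called member. NK and innate markers had 2 of 9 higher and 3 lower (3 and 4 adjusted over the list alone, mean -0.78, adjusted p = 0.587). Il2rb fell from 51.2 ± 24.0 to 7.62 ± 1.73 CPM. Trdc, the constant part of the delta chain of gamma-delta T cells, rose from 102 ± 19.2 to 213 ± 40.4 CPM. Endothelial markers had 1 of 3 lower (1 adjusted over the list alone, mean -0.00, adjusted p = 0.547), which was Pecam1. Megakaryocyte and mast cell markers had 2 members tested (mean 0.99, 1 higher adjusted over the list alone), stromal markers 1 (1.25) and adipocyte markers none.

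The largest changes outside these lists were mostly decreases. Acvrl1, a TGF-beta family receptor, fell by 3.61 on the log2 scale, and Cd7, a T and NK cell surface protein, from 27.6 ± 14.0 to 2.32 ± 1.13 CPM. Slfn1 fell from 79.0 ± 10.2 to 7.07 ± 9.71 CPM. The interferon gene Ifi44 fell by 3.80 on the log2 scale and Pydc4 by 3.47. Most of the 8 higher genes ranked by size lost their call without at least 1 mouse. Mybl1, a MYB family transcription factor, had a log2 fold change of 1.25 (adjusted p = 0.0103, and 0.0504 without empty-vector mouse M312). Rad51c, of homologous recombination, had 1.55 (adjusted p = 0.0139, but 0.0604 without empty-vector mouse M315 and 0.0632 without TAL1 mouse M318).

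**Figure D2:**
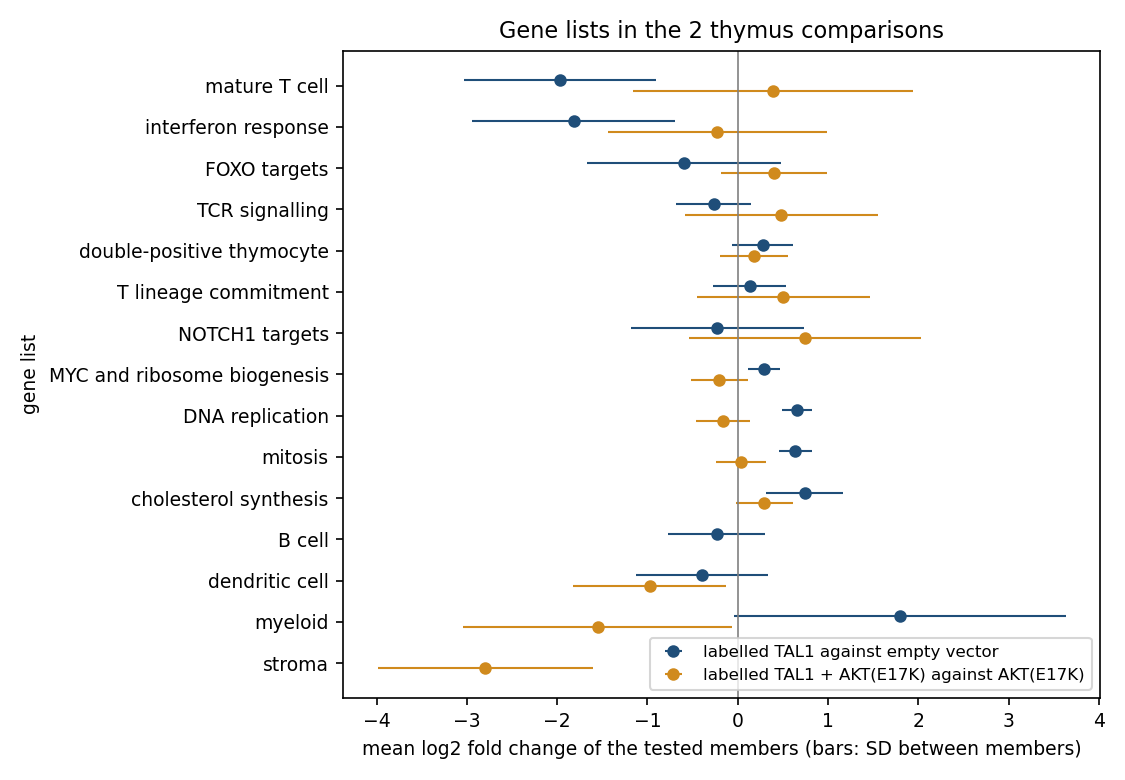
Mean log2 fold change of the tested members of 15 gene lists in the mice labelled TAL1 against empty vector and in the mice labelled TAL1 + AKT(E17K) against AKT(E17K), with bars for the SD between members. Mature T cell genes averaged -1.97 in the former comparison and 0.39 in the latter, and DNA replication genes 0.65 and -0.16.

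In the AKT(E17K) background, which asks what the TAL1 label adds to activated AKT, no gene passed the threshold with edgeR. List members with small p are therefore given as values. Il2ra, the interleukin-2 receptor alpha chain of early thymocytes (chromosome 2, 11642807 to 11693193), was 39.1, 64.3 and 45.0 CPM in the 3 AKT(E17K) mice and 512, 1326 and 308 CPM in those labelled AKT(E17K) with TAL1 (log2 fold change 3.86 ± 0.54, adjusted p = 0.218). Trib2, a pseudokinase counted among TAL1 targets (chromosome 12, 15791727 to 15816922), was 29.6 ± 12.5 and 167 ± 66.5 CPM (2.47 ± 0.40, adjusted p = 0.218). Lmo4, a partner of TAL1 complexes, was 80.2 and 362 CPM on average (2.17 ± 0.47, adjusted p = 0.373), and Cd2 was 5.61 ± 7.26 and 81.4 ± 28.3 CPM (3.75 ± 0.80, adjusted p = 0.373).

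edgeR called 0 of 9782 genes, with 709 at an unadjusted p under 0.05 and a smallest adjusted p of 0.218. DESeq2 called 76 (41 higher, 35 lower), among them Il2ra (adjusted p = 2.94e-14), Trib2 (8.71e-07) and Lmo4 (0.000339). It also called Gimap6 (0.00378), Itgb7 (0.0129), Foxo1 (0.0173), Irf8 (0.0256) and Epcam (0.0428). In 1 simulated draw for this comparison 13 DESeq2 calls were false (18.3%), against 2 with edgeR (4.35%). With so few false calls in 1 draw, these shares are rough. Without filtering of low counts edgeR called 30 (22 higher, 8 lower). Without AKT(E17K) mouse m124 it called 8, and without mouse m119 of the AKT(E17K) with TAL1 group it called 1. Notch1 was 548 ± 114 CPM in AKT(E17K) mice and 653 ± 281 CPM with the TAL1 label.

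No list had a member called by edgeR in this comparison, and every adjusted p with an estimated correlation was at least 0.806. With the preset correlation, camera called NOTCH1 targets (11 tested, mean 0.75, adjusted p = 0.0191, 4 higher adjusted over the list alone) and T lineage commitment (18, mean 0.51, adjusted p = 0.0191, 1 higher adjusted over the list alone). Dtx1 was 243 ± 18.8 and 602 ± 376 CPM. Hes1, a repressor that NOTCH1 switches on, was 29.3 ± 11.8 and 66.4 ± 24.8 CPM, and both are in these lists. Cholesterol synthesis (20, mean 0.30, adjusted p = 0.0191) and FOXO targets (15, mean 0.41, adjusted p = 0.039) were also called upward. Dendritic markers were called downward (8, mean -0.97, adjusted p = 0.0191, 1 lower adjusted over the list alone). Each of these list calls ended without at least 1 mouse. Without AKT(E17K) mouse m121 the adjusted p values were 0.0918 for T lineage commitment, 0.252 for FOXO targets, 0.279 for cholesterol synthesis and 0.0918 for dendritic markers. Without mouse m122 it was 0.124 for FOXO targets, and without mouse m124 it was 0.265 for NOTCH1 targets and 0.206 for cholesterol synthesis. In the AKT(E17K) with TAL1 group it was 0.059 for cholesterol synthesis without mouse m116, and 0.0522 for dendritic markers without mouse m119. Without mouse m117 it was 0.167 for T lineage commitment, 0.0892 for NOTCH1 targets, 0.394 for FOXO targets and 0.0875 for dendritic markers. Scaling by library size only also ended the call of FOXO targets (adjusted p = 0.0556).

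The remaining lists were not called. Mature T cell genes had a mean of 0.39 (13 tested, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.125). Members had Gimap6 at 5.06 and 28.01 CPM on average and Itgb7, an integrin of gut-homing T cells, at 4.14 ± 0.271 and 26.4 ± 20.2 CPM. TAL1 complex partners averaged 0.32 (15, 1 higher adjusted over the list alone, adjusted p = 0.28), TAL1 targets 0.41 (10, 2 higher adjusted over the list alone, adjusted p = 0.125). T cell receptor signalling averaged 0.48 (22, 1 higher adjusted over the list alone, adjusted p = 0.15), double-positive thymocyte genes 0.18 (18, adjusted p = 0.125) and E protein targets 0.21 (15, adjusted p = 0.629). DNA replication averaged -0.16 (21, adjusted p = 0.149), mitosis 0.04 (21, adjusted p = 0.69), MYC and ribosome biogenesis -0.20 (22, adjusted p = 0.491). PI3K/AKT components averaged 0.10 (22, adjusted p = 0.648), glycolysis -0.11 (18, adjusted p = 0.68), ATF4 genes -0.33 (17, adjusted p = 0.245) and p53 targets 0.06 (13, adjusted p = 0.625). For 3 small or mixed lists the mean and median differed in sign. They were early progenitors -0.12 and 0.23 (3, adjusted p = 0.514), interferon genes -0.23 and 0.07 (10, adjusted p = 0.69), and immediate early genes -0.02 and 0.11 (9, upward test direction, adjusted p = 0.918). The BCL2 family had a mean of 0.03 and a median of -0.00 (11, adjusted p = 0.625).

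Some stromal and myeloid markers were highest in 1 mouse of this experiment, and others were not. AKT(E17K) mouse m121 had 137 CPM of the collagen gene Col1a1, 622 CPM of the myeloid gene Lyz2 and 226 CPM of the macrophage gene C1qa. AKT(E17K) mice m122 and m124 had 0 and 2.06 CPM of Col1a1, 13.7 and 48.3 CPM of Lyz2, and 1.58 and 9.77 CPM of C1qa. Lyz2 was 145 CPM in mouse m116 of the AKT(E17K) with TAL1 group. S100a8, a neutrophil gene, was 18.9 CPM in mouse m121 against 56.6 in m124, 81.0 in m116 and 49.1 in m117. Stromal markers averaged -2.80 (7 tested, adjusted p = 0.223), myeloid markers -1.55 (12, adjusted p = 0.149), NK and innate markers -0.90 (5, adjusted p = 0.514). Erythroid markers averaged -0.47 (7, adjusted p = 0.648), endothelial markers -0.49 (3, adjusted p = 0.625) and thymic epithelial markers -1.21 (4, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.68). B cell, megakaryocyte and adipocyte markers had 1 tested member each, at -2.46, -2.74 and -2.72. Each had an unadjusted edgeR p under 0.05, as did 709 of the 9782 genes tested here, and none was called. Mitochondrially encoded mRNAs had no tested member in this table.

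Whether the effect of the TAL1 label differed between the AKT(E17K) and the empty-vector experiments was tested with an interaction contrast. Of 10947 genes 18 differed, each with a more positive effect beside AKT(E17K). Klf2 fell from 144 to 35.5 CPM with the TAL1 label alone, against 5.28 ± 0.48 and 15.6 ± 5.81 CPM beside AKT(E17K) (interaction log2 fold change 3.59, adjusted p = 0.00575). Add3, a cytoskeletal adducin (chromosome 19, 53140443 to 53247399), was 166 and 71.4 CPM in the empty-vector experiment, and 6.01 and 20.7 CPM beside AKT(E17K) (2.998, adjusted p = 0.00074). Cd2 was 311.6 and 177 CPM, and 5.61 and 81.4 CPM beside AKT(E17K) (4.54, adjusted p = 0.0346).

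The interaction test called no gene in the other direction, with 1189 genes at an unadjusted p under 0.05, and DESeq2 called 175 (123 positive, 52 negative). Of the 18 genes, edgeR called 13 lower in the mice labelled TAL1, none was called by edgeR beside AKT(E17K), where DESeq2 called 10, and 4 are mature T cell list members (Klf2, Gimap4, Gimap6 and Itgb7). The median log2 fold change was 2.52 beside AKT(E17K) over the 18 genes, and -1.14 in the empty-vector experiment over the 16 tested there. The interaction was 4.08 for Gimap4, 3.13 for Gimap6 and 4.53 for Itgb7. The other genes, chosen after their values were seen, were Gimap8 (4.77), Fam65b (3.99), H2-Q2 (3.24), Ctsw (3.06), Shisa5 (3.01), and Agfg1 (2.92). Chosen likewise were Ms4a6b (1.89), Anxa6 (1.81), Msn (1.25), Sidt1 (7.59), Gm973 (8.75) and Abcb1a (9.71). Gimap8 and H2-Q2 belong to families of similar sequence. Gimap8, Sidt1, Gm973 and Abcb1a had counts of 0 to 7 in the AKT(E17K) mice and Cd2 had 1, 5 and 54, so their fitted changes are not precise. Others had few counts there too, with 11, 2 and 12 for H2-Q2 and 12, 8 and 17 for Itgb7. Klf2 had 17, 9 and 22 and Add3 19, 10 and 26. Agfg1, Shisa5, Anxa6 and Msn had at least 100 in each of these mice. The count of 18 depended on single mice. It was 11 without AKT(E17K) mouse m121, of which 8 were among the 18, 3 without m122 and 173 without m124. It was 2 and 49 without mice m116 and m119 of the AKT(E17K) with TAL1 group. Of these calls 68 of the 173 were negative, as were 10 of the 49, 1 of the 3 without m122 and 3 of the 19 called without m117. The count was 2 without any of the 3 empty-vector mice and 2 without TAL1 mouse M317 or M318. The contrast sets separate experiments against each other, so AKT(E17K) is not the only difference between them. Reference levels were far apart too. Notch1, chosen after its values were seen, was 8.91 CPM in empty-vector mice and 548 CPM in AKT(E17K) mice. Klf2, Cd2 and Add3 were 144, 311.6 and 166 CPM against 5.28, 5.61 and 6.01 CPM. The contrast cannot tell such a difference between reference groups or tables from a changed effect of TAL1.

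**Figure D3:**
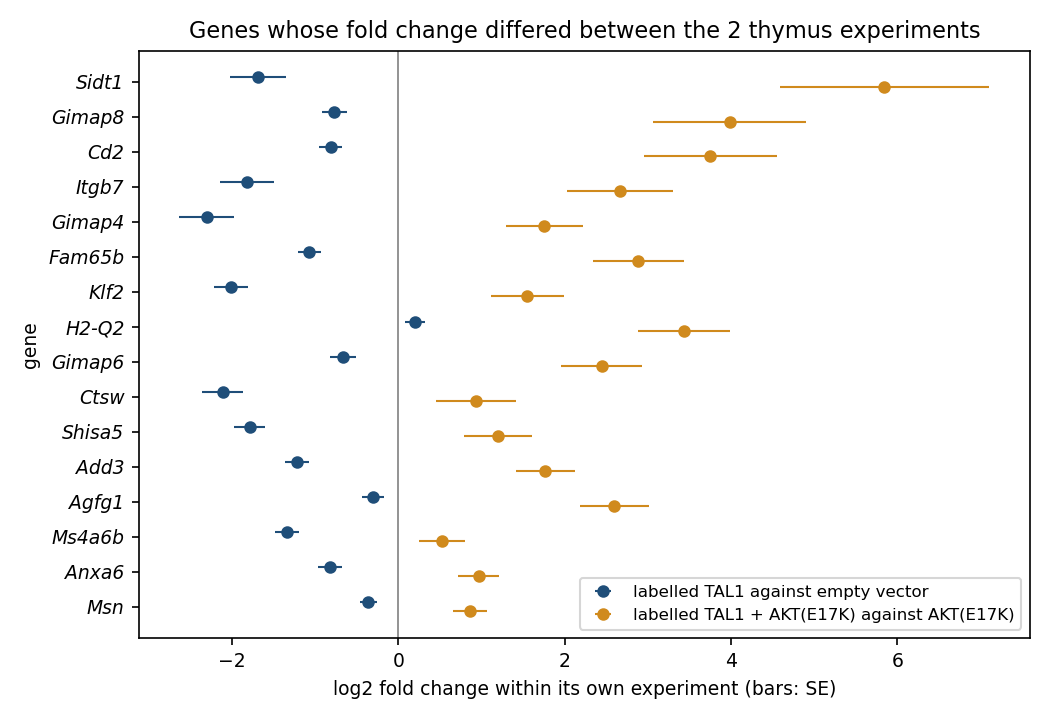
Log2 fold change with SE for the TAL1 label in each thymus experiment, for 16 of the 18 genes whose effect differed between the experiments. Klf2 was -2.02 in the mice labelled TAL1 against empty vector and 1.55 in the mice labelled TAL1 + AKT(E17K) against AKT(E17K).

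In ProT cells the comparisons with 0 h follow the response to tamoxifen over time. At 6 h no gene passed the threshold, yet the genes of cholesterol synthesis moved up together. Of 20 tested members none was called over all genes, but 16 were higher when adjusted over the list alone (mean log2 fold change 0.48, camera adjusted p = 3.13e-19, adjusted p = 0.0228 with an estimated correlation). Msmo1, a sterol oxidase (chromosome 8, 64718139 to 64733792), was 50.3 ± 1.02 CPM at 0 h and 74.4 ± 4.58 CPM at 6 h (0.56 ± 0.11, adjusted p = 0.196). Hmgcs1 was 144 and 215 CPM (0.58, adjusted p = 0.511). edgeR called 0 of 13610 genes with 734 at an unadjusted p under 0.05, and DESeq2 called 1, which was Msmo1 (adjusted p = 0.0477). Akt1 was 102 ± 12.0 CPM at 0 h and 120.6 ± 22.2 CPM at 6 h (0.24, adjusted p = 0.916). No other list was called at 6 h: mitosis had a camera adjusted p of 0.0972 and a mean of 0.12.

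At 12 h 14 of 17 glycolysis genes and 16 of 21 mitosis genes were higher, although both list calls were lost with an estimated correlation (adjusted p = 0.101). Tpi1, an enzyme of glycolysis (chromosome 6, 124810586 to 124814296), rose from 29.1 ± 4.35 to 102 ± 10.7 CPM (log2 fold change 1.78 ± 0.15, adjusted p = 3.75e-08), and Aldoa, another (chromosome 7, 126795234 to 126800751), from 165 to 452 CPM. Of 17 glycolysis genes 14 were higher and none lower (15 higher adjusted over the list alone, mean 1.02, camera adjusted p = 7.06e-16, adjusted p = 0.101 with an estimated correlation). Pkm was up by 1.37 and Ldha by 1.11. Of 21 mitosis genes 16 were higher (19 adjusted over the list alone, mean 0.57, camera adjusted p = 2.91e-13, adjusted p = 0.101 with an estimated correlation). Ccnb2, a mitotic cyclin, rose from 28.6 to 53.5 CPM. Of 21 DNA replication genes 10 were higher (12 adjusted over the list alone, mean 0.38, camera adjusted p = 3.14e-06, adjusted p = 0.293 with an estimated correlation). Tal1 counts were lower at that time, so none of these rises went with more counted Tal1.

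Some T lineage genes were higher at 12 h. T lineage commitment had 6 of 17 higher and 1 lower (8 and 1 adjusted over the list alone, mean 0.22, camera adjusted p = 0.00502, adjusted p = 0.412 with an estimated correlation). NOTCH1 targets had 5 of 12 higher (6 adjusted over the list alone, mean 0.43, camera adjusted p = 0.0256, adjusted p = 0.412 with an estimated correlation). This call ended without 0 h library 3 (adjusted p = 0.0605) or 12 h library 1 (adjusted p = 0.0948) and with scaling by library size only (adjusted p = 0.0857). Il2ra rose from 523 ± 33.7 to 1026 ± 95.7 CPM, Hes1 from 56.5 to 108 CPM and Notch1 (chromosome 2, 26457903 to 26516663) from 81.2 ± 4.57 to 114 ± 5.28 CPM. Among TAL1 complex partners 3 of 19 were lower (3 higher and 4 lower adjusted over the list alone, mean -0.09, median 0.02, camera adjusted p = 0.704). They were Tal1, Ldb1 (114 to 69.9 CPM) and Lmo2 (11.1 to 4.28 CPM). Early progenitor genes had 3 of 14 higher and 4 lower (5 and 4 adjusted over the list alone, mean 0.02, median -0.06), with Erg up by 1.41 and Mef2c down at -1.14. Mitochondrially encoded mRNAs had 4 of 13 lower (4 adjusted over the list alone, mean -0.38, camera adjusted p = 0.00316, adjusted p = 0.66 with an estimated correlation). This call ended without 12 h library 1 (adjusted p = 0.112). Megakaryocyte and mast cell markers had 2 of 5 higher (4 adjusted over the list alone, mean 0.78, camera adjusted p = 0.00502, adjusted p = 0.101 with an estimated correlation). With no filter on low counts their mean was -0.10 and the call ended (adjusted p = 0.178). Cpa3, a mast cell protease, rose from 257 to 424 CPM. Akt1 was 121.3 CPM (0.24, adjusted p = 0.213).

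At 12 h 1635 of 13610 genes were called (861 higher, 774 lower), and 309 changed by at least 1 (93 higher, 216 lower). The count was 918 without 0 h library 1 and 819 without 0 h library 2. With scaling by library size only it was 2380, split 2041 higher to 339 lower, and the median of all genes moved to 0.18 on the log2 scale, so these changes are relative to the typical gene. The share of counts on the rRNA-like genes Rn18s-rs5 and Yam1 was 13.2% to 17.3% at 0 h and 5.83% to 11.1% at 12 h, and without these genes 1625 genes were called. Without them and with library size only it was 1501 (959 higher, 542 lower, median 0.05), so much of the skew toward higher calls under that scaling went with them.

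At 18 h the immediate early genes, which respond to signals and to handling within minutes, were higher. Egr1 (chromosome 18, 34859823 to 34864984) rose from 4.96 ± 2.34 to 79.8 ± 19.5 CPM (log2 fold change 3.99 ± 0.26, adjusted p = 5.96e-11), Junb from 13.1 to 41.0 CPM and Ier2 from 24.5 to 47.6 CPM. Egr1 had been called lower at 12 h than at 0 h (log2 fold change -1.60 ± 0.43, edgeR adjusted p = 0.0138). Of 14 immediate early genes 6 were higher and none lower (7 higher adjusted over the list alone, mean 0.87, camera adjusted p = 1e-05, adjusted p = 0.041 with an estimated correlation). Glycolysis had 13 of 17 higher (13 adjusted over the list alone, mean 0.71, camera adjusted p = 4.12e-11, adjusted p = 0.155 with an estimated correlation). Pdk1, which directs pyruvate away from mitochondria, rose from 50.9 to 89.7 CPM. Mitosis had 9 of 21 higher (15 adjusted over the list alone, mean 0.39, camera adjusted p = 5.01e-08, adjusted p = 0.261 with an estimated correlation). DNA replication had 5 of 21 (9 adjusted over the list alone, mean 0.27, camera adjusted p = 0.000571, adjusted p = 0.521 with an estimated correlation).

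Cholesterol genes were called again at 18 h, with 6 of 20 higher and 1 lower (6 and 2 adjusted over the list alone, mean 0.15, camera adjusted p = 0.0452, adjusted p = 0.573 with an estimated correlation). Msmo1 rose from 50.3 to 72.2 CPM. The list call ended without 0 h library 2 (adjusted p = 0.175) or 3 (adjusted p = 0.0521), without 18 h library 1 (adjusted p = 0.111) or 3 (adjusted p = 0.0769), and with scaling by library size only (adjusted p = 0.0816, and 0.0592 without the rRNA-like genes as well). It also ended with a filter at a mean of 5 CPM (adjusted p = 0.0767) and with only the 0 and 18 h libraries in the fit (adjusted p = 0.0798). ATF4 genes had 2 of 19 higher (2 adjusted over the list alone, mean 0.19, camera adjusted p = 0.0383, adjusted p = 0.627 with an estimated correlation). The call was lost without 0 h library 1 (adjusted p = 0.135) or 18 h library 1 (adjusted p = 0.111) and with library size only (adjusted p = 0.0691, and 0.0509 without the rRNA-like genes as well). It was lost too with the filter at 5 CPM (adjusted p = 0.0710), with only the 0 and 18 h libraries (adjusted p = 0.0583) and without 0 h library 1 and 6 h library 1 together (adjusted p = 0.143). Mitochondrially encoded mRNAs had 4 of 13 lower (10 adjusted over the list alone, mean -0.45, camera adjusted p = 0.000219, adjusted p = 0.573 with an estimated correlation). Megakaryocyte and mast cell markers had 2 of 5 higher (3 adjusted over the list alone, mean 0.76, camera adjusted p = 0.003, adjusted p = 0.0859 with an estimated correlation). With no filter on low counts this call ended (mean 0.26, adjusted p = 0.0682). FOXO targets were not called as a list, although Bcl2l11, a killer of the BCL2 family, rose from 76.4 to 116.2 CPM and Cdkn1b, an inhibitor of the cell cycle, from 109.8 to 158 CPM. Akt1 was 121.3 ± 14.2 CPM (0.24, adjusted p = 0.242).

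At 18 h 1200 genes were called (666 higher, 534 lower), and 176 changed by at least 1 (59 higher, the remainder lower). The count was 619 without 0 h library 1, 471 without 0 h library 2, 419 without 18 h library 1 and 769 without 18 h library 2, and it was 2244 when only the 0 and 18 h libraries were fitted. With library size only 1368 genes were called, 1122 higher and 246 lower, with the median of all genes at 0.13. Under that scaling and without the rRNA-like genes it was 1069 (696 higher, 373 lower). With TMM and without these genes it was 1191 (671 higher, 520 lower).

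At 24 h the mitosis genes had risen almost without exception. Of 21 members 20 were higher and 1 was not called (20 higher adjusted over the list alone, mean 0.69, camera adjusted p = 3.24e-14, adjusted p = 0.123 with an estimated correlation). Top2a rose from 344 ± 2.56 to 642 ± 17.4 CPM (log2 fold change 0.90 ± 0.12, adjusted p = 1.13e-05), Plk1, a mitotic kinase, from 37.1 to 70.1 CPM, and Ccnb2 (chromosome 9, 70407692 to 70421547) from 28.6 to 54.9 CPM. DNA replication had 14 of 21 higher (19 adjusted over the list alone, mean 0.50, camera adjusted p = 6.2e-08, adjusted p = 0.212 with an estimated correlation). Cdc6, which loads the replication helicase, rose from 21.1 to 41.7 CPM. Tal1 counts were at their lowest mean, 2019 ± 52.6 CPM, against 3007 ± 103 CPM at 0 h.

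Some members of growth and metabolism lists were higher too. MYC and ribosome biogenesis had 7 of 22 higher (8 adjusted over the list alone, mean 0.28, camera adjusted p = 0.0026, adjusted p = 0.549 with an estimated correlation). Npm1, a nucleolar chaperone, rose from 555 to 841 CPM and Odc1 from 38.6 to 66.0 CPM. Glycolysis had 9 of 17 higher (10 adjusted over the list alone, mean 0.48, camera adjusted p = 1.68e-05, adjusted p = 0.461 with an estimated correlation), with Tpi1 at 55.4 ± 5.41 CPM. ATF4 and amino acid genes had 6 of 19 higher (12 adjusted over the list alone, mean 0.38, camera adjusted p = 0.000275, adjusted p = 0.461 with an estimated correlation). Mthfd2, of mitochondrial folate metabolism, rose from 58.5 to 106 CPM. Mitochondrially encoded mRNAs had 12 of 13 lower (13 adjusted over the list alone, mean -0.66, camera adjusted p = 4.41e-06, adjusted p = 0.461 with an estimated correlation). The log2 fold change of mt-Nd3 was -0.88 and that of mt-Nd5 -0.71. The composition of the libraries moved too: mitochondrial rRNA was 6.28% to 7.23% of counts at 0 h and 4.40% to 4.64% at 24 h, and the rRNA-like genes 13.2% to 17.3% and 9.39% to 11.3%. Reads in no annotated feature were 21.1% to 22.2% and 17.8% to 18.4%. Megakaryocyte and mast cell markers had 3 of 5 higher (3 adjusted over the list alone, mean 0.83, camera adjusted p = 0.00542, adjusted p = 0.123 with an estimated correlation). With no filter the mean was -0.02 and the call ended (adjusted p = 0.212). Cpa3 rose from 257 ± 14.0 to 449 ± 18.2 CPM and Itga2b from 23.0 ± 7.26 to 38.4 ± 0.752 CPM.

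Among regulators, TAL1 complex partners had 2 of 19 higher and 3 lower (3 and 4 adjusted over the list alone, mean -0.02, median 0.03 with an upward test direction, adjusted p = 0.979). Lyl1, a close relative of TAL1, rose from 54.8 to 87.6 CPM and Ldb1 fell from 114 to 66.9 CPM. TAL1 target genes had 4 of 12 higher and 1 lower (5 and 1 adjusted over the list alone, mean 0.03, adjusted p = 0.664). NOTCH1 targets had 6 of 12 higher and 1 lower (6 and 1 adjusted over the list alone, mean 0.27, adjusted p = 0.239). T lineage commitment had 5 of 17 higher and 1 lower (6 and 1 adjusted over the list alone, mean 0.14, adjusted p = 0.174), so neither list was called at this time. Their members Il2ra, Hes1, Nrarp and Dtx1 rose by 1.06, 0.88, 0.998 and 1.11. Early progenitor genes had 4 of 14 higher and 3 lower (4 and 4 adjusted over the list alone, mean 0.09, adjusted p = 0.522). Erg, an ETS factor of progenitors, rose from 9.83 to 21.9 CPM and Mef2c fell from 37.9 to 17.7 CPM. Among PI3K/AKT components, with 2 of 24 higher and 2 lower (2 and 3 adjusted over the list alone, mean -0.04, adjusted p = 0.635), Eif4ebp1, which mTOR controls, rose from 32.2 to 58.4 CPM. Akt1 was 135 ± 8.97 CPM (0.39, adjusted p = 0.0275). This call was lost without 0 h library 1 (adjusted p = 0.0971) or 2 (adjusted p = 0.133) and without 24 h library 1 (adjusted p = 0.0537) or 2 (adjusted p = 0.117).

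Further lists were not called at 24 h. They were double-positive thymocyte genes (14 tested, 1 higher, 3 lower, mean -0.09, adjusted p = 0.544), mature T cell genes (15, 2 higher, 2 lower, mean -0.06, adjusted p = 0.859). They were also T cell receptor signalling (20, 1 higher, 5 lower, mean -0.15, adjusted p = 0.24) and E protein targets (12, 1 higher, 1 lower, mean -0.00 with an upward test direction, adjusted p = 0.979). FOXO targets (18, 2 higher, 2 lower, mean -0.12, adjusted p = 0.317), cholesterol synthesis (20, 3 higher, 1 lower, mean 0.04, adjusted p = 0.544), p53 targets (14, 1 lower, mean 0.00, median -0.01, adjusted p = 0.951) and interferon genes (14, 1 higher and none adjusted over the list alone, mean 0.12, adjusted p = 0.622) were not called either. Nor were immediate early genes (14, 3 higher, 5 adjusted over the list alone, mean 0.17, adjusted p = 0.189) or the BCL2 family (12, none called, mean -0.01, adjusted p = 0.951). Of the cell type markers, B cell (3 tested, 1 lower, mean -0.72, adjusted p = 0.189), myeloid (10, 3 lower, mean -0.44, adjusted p = 0.359) and dendritic (8, 1 higher, 2 lower, mean -0.16, adjusted p = 0.664) lists had called members. So did erythroid (7, 1 higher, 1 lower, mean -0.07, median 0.08, adjusted p = 0.951) and NK and innate markers (11, 1 higher, 2 lower, mean -0.27, median 0.08, adjusted p = 0.979). Thymic epithelial (3, mean -0.02, median 0.03 with an upward test direction, adjusted p = 0.979) and endothelial markers (4, 1 lower, mean -0.27, adjusted p = 0.317) were also measured, and stromal and adipocyte markers had 1 member each, at 0.04 and -0.16. Adjusted over the list alone the counts were 2 higher and 4 lower for double-positive genes, 0 and 1 for E protein targets, 1 and 2 for erythroid and 1 and 3 for NK markers. For the other lists without such counts here they were unchanged. Within these lists S100a8 fell from 24.2 to 9.95 CPM and Ighm from 17.8 to 6.92 CPM.

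The largest rises at 24 h were in the histone genes Hist1h2ah (64.2 ± 37.1 to 292 ± 132 CPM) and Hist1h2ag (80.8 ± 40.0 to 320.02 ± 137 CPM). Near-identical copies make the assignment of reads to them uncertain. Podxl, a sialomucin of progenitor cells (chromosome 6, 31519488 to 31563981), rose from 10.2 ± 1.88 to 33.8 ± 2.21 CPM (log2 fold change 1.76 ± 0.19, adjusted p = 1.76e-06). Aldh1b1, a mitochondrial aldehyde dehydrogenase, rose from 24.5 ± 3.53 to 80.9 ± 2.35 CPM, and Serpina3g by 1.82. Among the largest falls, Slc24a3, a sodium, potassium and calcium exchanger (chromosome 2, 145167754 to 145642166), went from 29.7 ± 2.24 to 9.64 ± 1.40 CPM. Cmah fell from 37.5 ± 6.31 to 12.4 ± 1.67 CPM, Ahnak from 18.1 ± 1.71 to 4.97 ± 1.03 CPM and Scn4b from 8.36 ± 1.46 to 1.70 ± 0.753 CPM.

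At 24 h 2549 genes were called (1283 higher, 1266 lower), and 425 changed by at least 1 (308 lower, the remainder higher). The count was 1562 without 0 h library 1, 1447 without 0 h library 2, 1682 without 24 h library 1 and 1665 without 24 h library 2. With library size only it was 3182, split 2560 to 622, with the median of all genes at 0.17. Under that scaling and without the rRNA-like genes it was 2690 (1827 higher, 863 lower). With TMM and without these genes it was 2556 (1294 higher, 1262 lower). The test over all times called 2455 genes, 1234 of them higher and 1221 lower at the time of their largest change. With library size only it called 2561 (1961 higher, 600 lower), where the median of those largest changes was 0.30 against -0.12.

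Calls at different times overlapped, and these comparisons share the 0 h libraries. The 12 and 18 h comparisons shared 492 higher and 353 lower genes, 12 and 24 h shared 674 and 585, and 18 and 24 h shared 541 and 423. Called in opposite directions were 2 genes at 12 and 18 h, Egr1 and Zfp36, and 1 at 12 and 24 h, Egr1. Independent lists of the sizes called would share 42.1 and 30.4 higher and lower genes, 81.2 and 72.0, and 62.8 and 49.7. Simulated groups against the same controls shared 0, but they held no true change to call, so this 0 does not measure what the controls add. The correlation of log2 fold changes was 0.80, 0.81 and 0.79, against 0.56, 0.57 and 0.55 in the simulated groups. The covariance of log2 fold changes was 0.155, 0.180 and 0.167, against simulated values near 0.038 (0.0382, 0.0380 and 0.0382), so the differences were 0.117, 0.142 and 0.129. The 3 libraries at 0 h cannot be divided so that both parts keep replicates, and part of the overlap may come from these shared controls.

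**Figure D4:**
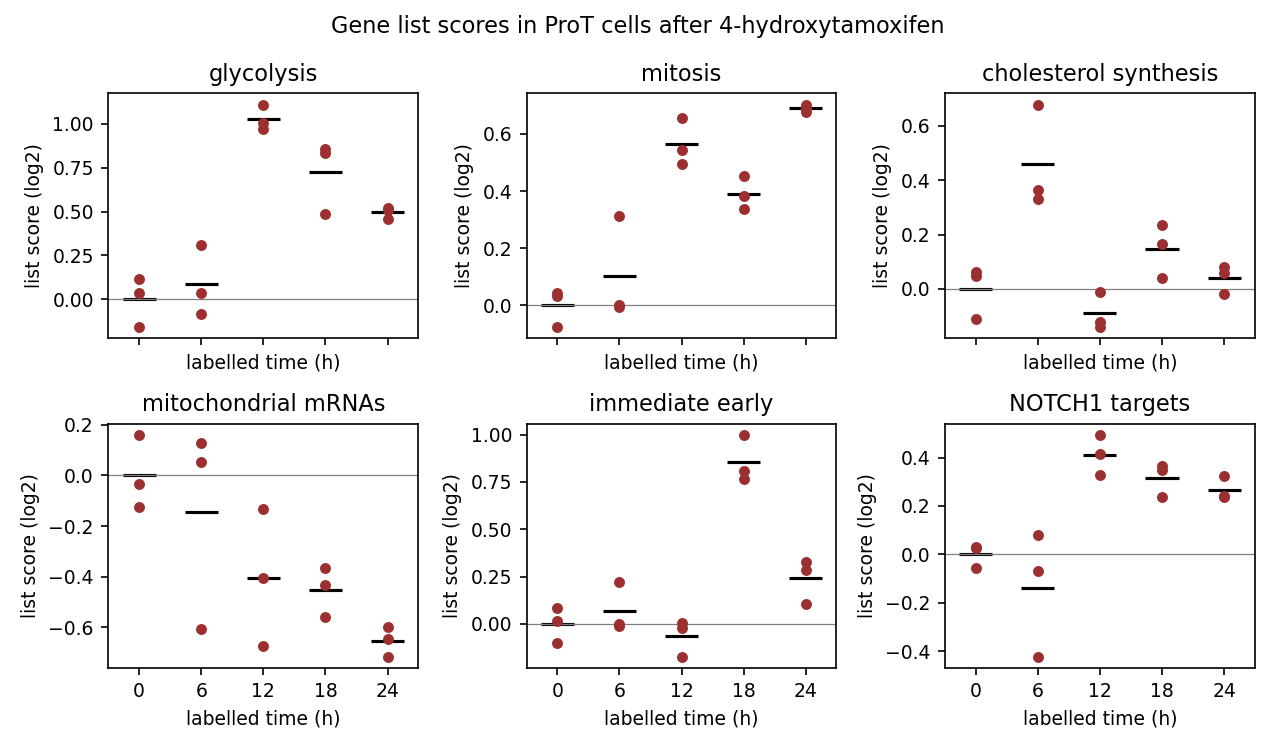
List score (log2, with the 0 h mean at 0) of each ProT library by labelled hours after tamoxifen for glycolysis, mitosis, cholesterol synthesis, mitochondrial mRNAs, immediate early genes and NOTCH1 targets, with lines through the means. Glycolysis averaged 1.02 at 12 h and 0.48 at 24 h against 0 h, and mitosis 0.57 and 0.69.

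The thymus with the TAL1 label and ProT cells at 24 h share no libraries, and their calls overlapped. Among 11056 genes tested in both, 138 were higher in both where independent lists would share 26.2 (Fisher exact test, adjusted p = 2.54e-69). There were 60 lower in both against 30.3 (adjusted p = 3.45e-07). The Fisher test treats genes as independent, which they are not, so its p values here and below may be far too small. Genes higher in thymus and lower in ProT cells numbered 11 against 25.8 (adjusted p = 0.00137), and the reverse 21 against 30.7 (adjusted p = 0.0661). With DESeq2 the reverse was called too, at 25 against 42.4 (adjusted p = 0.00696). Top2a, Plk1, Mki67, Rrm2, Uhrf1 and Mthfd2 were among the genes named as higher in both, and S1pr1 and Id2 among those lower in both. Over all these genes the correlation of log2 fold changes was 0.19 (Spearman 0.22), across genes that are not independent replicates. Restricting calls to changes of at least 1 left 1 gene higher in both and 8 lower in both, against 0.121 and 3.52 for independent lists. Neither passed the Fisher test (adjusted p = 0.229 and 0.1005). The AKT(E17K) comparison had no edgeR calls to overlap. Among its DESeq2 calls, 9 higher genes were lower in the mice labelled TAL1, against 1.04 for independent lists (Fisher adjusted p = 1.88e-06). There were 6 lower in ProT cells at 24 h, against 2.27 (Fisher adjusted p = 0.0452). Across genes the correlation of log2 fold changes between the thymus experiments was 0.00256.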

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

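The tests of the genes called without mouse m121, of tamoxifen or culture time, of other differences between the thymus experiments, of the share of mature T cells and of blood cells were chosen after seeing the results they measure, as were the comparisons of consecutive times.

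The effect of the TAL1 label differed between the AKT(E17K) and empty-vector thymus experiments for 18 genes by the interaction test. The interaction log2 fold changes were 9.71 for Abcb1a, 8.75 for Gm973, 7.59 for Sidt1, 4.77 for Gimap8, 4.54 for Cd2, 4.53 for Itgb7, 4.08 for Gimap4, 3.99 for Fam65b and 3.59 for Klf2. They were 3.24 for H2-Q2, 3.13 for Gimap6, 3.06 for Ctsw, 3.01 for Shisa5, 2.998 for Add3, 2.92 for Agfg1, 1.89 for Ms4a6b, 1.81 for Anxa6 and 1.25 for Msn. Those of Abcb1a, Gm973, Sidt1 and Gimap8, with 0 to 7 counts in AKT(E17K) mice, and of Cd2, with 1, 5 and 54, are not precise. H2-Q2, Itgb7, Klf2 and Add3, among others, also had few counts in those mice. There were 9 lists called at the preset correlation and none with an estimated one, whose adjusted p is given beside each mean. They were mature T cell genes at 2.28 (0.166), T cell receptor signalling at 0.74 (0.86), NOTCH1 targets at 1.21 (0.703), FOXO targets at 0.78 (0.657) and interferon genes at 0.66 (0.703). The others were MYC and ribosome biogenesis at -0.47 (0.86), DNA replication at -0.67 (0.544), mitosis at -0.57 (0.761) and B cell markers at -1.46 (0.498). At the preset correlation, leaving out 1 mouse ended the call of T cell receptor signalling for AKT(E17K) mice m121 and m122 (adjusted p = 0.0901 and 0.0641), for mouse m117 of the AKT(E17K) with TAL1 group (0.329), for empty-vector mouse M312 (0.0709) and for TAL1 mouse M318 (0.105). That of MYC and ribosome biogenesis ended without m121, m122, m117 or M318 (adjusted p = 0.175, 0.449, 0.339 and 0.0932). NOTCH1 targets lost theirs without AKT(E17K) mouse m124, m117 or TAL1 mouse M317 (adjusted p = 0.232, 0.113 and 0.0592), and interferon genes without m124 (adjusted p = 0.0721), while without mouse m116 of the AKT(E17K) with TAL1 group the interferon mean was -0.71 although the test direction stayed upward.

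The median interaction log2 fold change over these 18 genes was 3.41 with all mice, 3.53 without AKT(E17K) mouse m121 and at lowest 3.17 without any 1 mouse, but these genes were picked as positive, so neither median excludes a part of foreign cells in m121 or of any single mouse. Refitted without m121, 11 genes were called, all 11 positive and 8 of them among the 18, so foreign cells in that mouse are excluded as the whole cause for those 8 and stay open for the others of the 18, while without AKT(E17K) mouse m124 68 of 173 calls were negative. With 0 tables that hold both kinds of mice, another difference between the experiments such as disease stage stays open, and the biological explanation, a changed effect of TAL1 beside activated AKT, is not separated from it. Over 100 splits of the mice into groups of the same sizes, 1 gave at least 18 genes, the real one, and the highest other gave 2. Other splits mix the labels, so differences between labels add to the spread within groups and hold calls down. These splits therefore do not exclude chance.

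Genes changed in ProT cells from 12 h on although Tal1 counts did not rise. With every library thinned to the shallowest, 2113.5 genes were called at 24 h as the median over 10 draws, against 2549, so unequal depth is excluded as the whole cause. Without the abundant rRNA-like genes Rn18s-rs5 and Yam1, 2690 were called under library size scaling, against 3182 with them, so their falling share is excluded as the whole cause at 24 h. At 12 h the count under that scaling went from 2380 to 1501, a fall of more than 1.5 times. By the limit used at 24 h, their share is therefore not excluded for the 12 h calls under that scaling. With TMM the 12 h count went from 1635 to 1625, with 1622 genes in common. TMM factors rest on the typical gene and hardly follow a few abundant ones. Near equality was thus likely whatever their share did, so it decides nothing about the 12 h calls. There were 0 libraries kept without tamoxifen beyond 0 h, so time in culture or tamoxifen itself stays open beside the biological explanation of the labels, an induced TAL1 protein, which counts of Tal1 RNA do not measure. The labels name CreER and LoxP, so removal of a floxed Tal1 sequence, a loss in place of a gain, was not tested and stays open beside the fall in Tal1 counts. Over 100 splits, 1 gave at least 2455 genes changed at any time, the real one, and the highest other gave 1882. Whether libraries of a time came from separate cultures is not known, so these splits cannot exclude a chance difference between cultures.

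Lower mature T cell (12 of 18) and interferon genes (14 of 20) and higher cell cycle genes (13 of 20 for DNA replication, 13 of 21 for mitosis) were called in the mice labelled TAL1, although each list lost its call with an estimated correlation (adjusted p = 0.352). Thinned to equal depth, a median of 637 genes was called, against 623, so depth is excluded. Reads in no annotated feature were 33.0% in each empty-vector mouse and 29.8% to 30.3% in the mice labelled TAL1. What part this difference between libraries took was not tested. All 18 of 18 mature T cell genes tested had a negative log2 fold change, so the pattern is consistent with a smaller share of mature T cells in these thymuses, an explanation found from the same values. B cell markers, of which few were tested, had a mean of -0.23, 1.73 above the mature T cell mean of -1.97. The SE of 0.37 was taken over genes, not mice. T cells from blood or lymph node need not bring B cells in proportion, so such cells in the empty-vector samples are not excluded. The biological explanation by the design, a block before the mature stage by TAL1, was not tested apart from cell shares.

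In ProT cells 1477 genes differed between 12 h and 6 h. The list means were 0.26 for T lineage commitment, 0.51 for NOTCH1 targets, 0.37 for DNA replication, 0.45 for mitosis, 0.94 for glycolysis, -0.57 for cholesterol synthesis, -0.27 for mitochondrial mRNAs and 0.54 for megakaryocyte and mast cell markers. With an estimated correlation their adjusted p values were 0.229, 0.192, 0.172, 0.132, 0.123, 0.123, 0.724 and 0.132. Between 18 h and 12 h 7 genes differed, among them Egr1 (5.59) and Zfp36 (1.94), chosen after their values were seen. The list means were -0.14 for T lineage commitment, -0.11 for DNA replication, -0.18 for mitosis, -0.31 for glycolysis, 0.24 for cholesterol synthesis and 1.003 for immediate early genes. With an estimated correlation their adjusted p values were 0.575, 0.626, 0.457, 0.457, 0.251 and 0.00233.

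Between 24 h and 18 h 22 genes differed, among them Egr1 (-2.17) and Zfp36 (-1.41), chosen after their values were seen. The list means were 0.21 for MYC and ribosome biogenesis, 0.23 for DNA replication, 0.30 for mitosis, -0.25 for FOXO targets, -0.24 for glycolysis, -0.11 for cholesterol synthesis, 0.19 for ATF4 genes, -0.695 for immediate early genes and -0.20 for mitochondrial mRNAs. With an estimated correlation their adjusted p values were 0.398, 0.335, 0.184, 0.184, 0.506, 0.643, 0.59, 0.028 and 0.643.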

How the results depend on the processing

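The thinning of libraries and the fits without rRNA-like genes or without 0 h library 1 and 6 h library 1 were tests chosen after seeing the data. No named gene that was called reversed, and no called list turned its test direction, although the mean of megakaryocyte and mast cell markers in ProT cells turned negative with no filter (-0.10 at 12 h and -0.02 at 24 h), as did that of interferon genes in the interaction test without mouse m116 (-0.71). Among named genes 7995 comparisons with an alternative kept the direction and the side of the threshold, 496 lost and 52 gained a call, and 98 values of uncalled genes changed sign. Among lists 2685 kept them, 98 lost and 51 gained a call, and 193 directions of uncalled lists turned. Among gene counts 102 stayed within 1.5 times of their value, 27 fell below and 11 rose above it.

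Requiring an absolute log2 fold change of at least 1 left 238 genes in the mice labelled TAL1 and, in ProT cells, 309 at 12 h, 176 at 18 h, 425 at 24 h and 484 at any time, by the construction of that limit. Without the filter on low counts 30 genes were called in the AKT(E17K) experiment, 1107 in the mice labelled TAL1 and 58 in the interaction test. DESeq2 called 76 in the AKT(E17K) experiment, 1 at 6 h and 175 in the interaction test, and a fit of only the 0 and 18 h libraries called 2244 at 18 h. The cause was not tested for these. Leaving out 1 library gave 0 to 8 genes in the AKT(E17K) experiment, 337 to 661 in the mice labelled TAL1, 819 to 1521 at 12 h, 419 to 1006 at 18 h, 1447 to 2281 at 24 h, 1810 to 3533 at any time and 2 to 173 in the interaction test. Without ProT 0 h library 1 and 6 h library 1 together, 1444 genes were called at 12 h, 1043 at 18 h, 2274 at 24 h, 3046 at any time and 0 at 6 h. Of the genes called with all libraries, 1262, 910, 2047 and 2244 were among them. Over the times compared with 0 h, 25 calls of named genes and 1 call of a list were lost, and a gene could lose its call at more than 1 time. With the estimated correlation 44 list calls were lost and 162 lists stayed the same.

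With the replicate number as a block, ProT counts were 1639 at 12 h, 1234 at 18 h, 2662 at 24 h and 2512 at any time, and 0 at 6 h, and no count moved by over 1.5 times. The libraries share only a number: the best partner of 5 of 15 libraries had the same number, and correlations of same-number pairs ran from -0.22 to 0.32. Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. The number of splits with at least as many genes as the real one was 10 in the AKT(E17K) experiment (real value 0, highest other 0), 10 at 6 h (0 and 0), 1 in the mice labelled TAL1 (623 and 0), 1 at 12 h (1635 and 0), 1 at 18 h (1200 and 0) and 1 at 24 h (2549 and 0). The shallowest library, with 2073752 counts, was in the AKT(E17K) experiment. On simulated data 60.9% of genes changed by 2 on the log2 scale were recovered there and 48.4% in the interaction test, and what depth and spread each took was not separated.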

Other observations

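Between 18 and 24 h a few genes differed in ProT cells, chosen after their values were seen and not tested as a group. Bnip3, which marks mitochondria for removal, fell by 1.27 on the log2 scale, Ankrd37 by 2.15, Pdk1 by 0.68, the histone demethylase Kdm3a by 0.79 and Ddit4, an inhibitor of mTOR, by 0.64. Bcl2l11 and Cdkn1b fell by 0.65 and 0.61, and Plk1 and Mthfd2 rose by 0.62 and 0.52. Between 12 and 18 h Cirbp, an RNA-binding protein induced by cold, rose by 0.71 and Dusp2 by 0.76. These genes were called by edgeR over all genes.

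On the first principal component, which held 39.6% of the variance, the empty-vector mice lay at -23.5 to -20.1 and the mice labelled TAL1 at 9.11 to 29.5. In the AKT(E17K) experiment the component held 38.3%, and in ProT cells 33.0%. There 6 h library 1 lay at -2.97, against -18.9 and -15.5 for the other 6 h libraries. On the second component 0 h library 1 lay at -20.1, against 9.04 and 2.35 for the other 0 h libraries. The rRNA-like genes Rn18s-rs5 and Yam1 took 0.0199% to 0.0313% of counts in the table of empty-vector mice and 5.83% to 17.3% in ProT cells.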
